A study of Mus musculus with 3 samples.

How the data were processed

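RNA from the dorsal cortex of mouse pups at postnatal day 4 was compared on 3 two-colour Agilent arrays, each with 1 wild-type and 1 Brpf1-deficient pup. Per the labels, Cy3 marks the wild-type and Cy5 the Brpf1-deficient sample on every array, so no dye swap exists. The labels number the pairs 1 to 3 and do not say whether pups of different pairs came from different litters. The RNA was amplified in a single round from 350 ng of total RNA, and the dyes were coupled afterwards, per the labels' protocols.

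The deposited scanner files hold the spot intensity in both colours, read by Agilent Feature Extraction 10.7.3.1 on a grid built on mm9, per the file headers. They give the median intensity of each spot and of its local background, without normalization, and no mean intensity of the spot, so the median was used where the mean had been planned. The processed intensity, per the file headers, is background-subtracted, spatially detrended and dye-normalized by the scanner software, and was used in an alternative only. The deposited log10 ratio is that of the processed red over the processed green signal. Flags mark spots well above background, saturated spots and non-uniform spots. All 3 arrays lie on 1 slide and come from 1 scan. No spot was saturated, and 4 to 6 spots per array were outliers.

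The authors also deposited a table of a comparison, with log2 fold changes, average log2 values, a t score, a log-odds score, a p-value and an adjusted p-value per spot. Per the submitters' processing notes limma was used. The background correction, the normalization, the filter and the direction of its ratio are not given in the sources used here. It lists 40000 of the 62976 spots, and the largest p-value in it is 0.458.

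Here the medians were background-corrected with normexp and an offset of 50 on all spots in limma 3.58.1 under R 4.3.3. Each array was normalized by loess with control spots at weight 0, and outlier spots were left out. The spots of a probe were averaged. A probe was kept if it was well above background in at least 1 channel on at least 2 of the 3 arrays, and each gene was represented by its probe of highest average intensity. The ratio is Cy5 over Cy3 on the log2 scale. It was tested against 0 with an intercept-only limma fit and moderated variances, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Values after ± are standard deviations over the 3 arrays.

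Where a probe was not well above background in a channel on any array, the fold is a lower bound. It was taken from channel values after loess and Aquantile normalization, as the mean of the brighter channel minus the mean of the higher of the dim value and the lowest signal among probes well above background on that array. Such bounds are open to dye bias.

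The scanner files used here hold no gene symbols. Of the 55681 non-control probes, 27656 were named through their RefSeq accession in a gene table of assembly GRCm38.p6, and 4082 through the authors' deposited table. The other 23943 kept the file's systematic name. Because that table stops at a p-value of 0.458, naming through it depends in part on the outcome. Among the 23232 genes tested, 15353 were named by RefSeq, 1444 by the authors' table and 6435 carry only a systematic name. The gene table's assembly differs from the grid's build, so it was used only for names and for which genes neighbour each other.

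The design, the alternatives, 32 gene lists and the rule for the genes named in the text were fixed before the data were examined. The rule names Brpf1, 6 genes recalled from the study's publication, and the 12 genes with the largest and the 12 with the smallest log2 ratio among genes past the threshold. These 24 genes had to move the same way on all 3 arrays and carry a symbol that is not a clone or model name. For each list described, the rule adds the 2 to 4 members with the smallest adjusted p. Some genes that the rule names are not reported here. The other probes of a reported gene are given where 1 of them had the opposite sign or less than 50% of the reported log2 ratio. Lists were tested with camera in limma at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with an estimated correlation and fry beside it. Counts adjusted over the list alone use the members of that list only. The lists are Hox clusters, genes recalled from the study, non-cortical patterning factors, partners of BRPF1 and related acetyltransferases, intermediate progenitors, radial glia, cell cycle, cell cycle inhibitors and p53 targets, upper-layer neurons, deep-layer and subplate neurons, axon guidance, hippocampus, interneurons, Cajal-Retzius cells, astrocytes, oligodendrocytes, microglia, endothelial cells, meninges, choroid plexus, erythroid cells, striatum, thalamus, early genes, hypoxia, interferon response, beta protocadherins, imprinted genes, synapse, germline, sex-linked genes and ribosomal proteins.

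The fit was tested on simulated data with 3 arrays and 23232 genes, of which 200 were changed by known folds. A first simulation, with each gene's moderated variance, called 50 of 50 genes at each of 1.5-fold, 2-fold, 4-fold and 8-fold, with 26 false calls among 23032 unchanged genes. That is more than the threshold of 0.05 allows on average. A second simulation, with variances drawn from limma's fitted prior, was added after the first had been seen. It called 45 of 50 genes changed 1.5-fold and 50 of 50 at each larger fold, with 8 false calls. A list of 20 simulated genes shifted by a log2 ratio of 0.5 was called by camera at the preset correlation, as were 0 of the other lists. It was not called with an estimated correlation. With 3 arrays that setting can miss a real shift, so a call lost under it does not decide whether a list shifted. The simulated genes varied independently of each other. The simulation therefore cannot show that the preset correlation limits false calls for lists whose members vary together. In the data the estimated correlation reached 0.963 for the striatum list. Multiplying the red signal of 200 probes by 4 raised their log2 ratio by a median of 1.95, which checks the direction of the ratio.

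Alternatives were the processed signals with median centring, no background correction, an offset of 16, median centring in place of loess, Aquantile with scale normalization, no filter or a stricter filter on dim probes, all probes or their mean, outlier spots kept, an intensity trend with robust variances, separate channels without the array as a block, other thresholds and leaving out each array in turn. After the data had been seen, 2 more were added: setting the median of each of 200 intensity bins to 0, and leaving out probes with a mean log2 intensity over 15.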

Results

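Gene expression in the dorsal cortex of mouse pups at postnatal day 4 was measured on 3 two-colour Agilent arrays, to ask which genes differ between wild-type pups and pups deficient in Brpf1. Brpf1 encodes a scaffold protein with bromodomain and PHD finger modules that holds together histone acetyltransferase complexes. Each array compared the RNA of 1 wild-type pup, labelled with Cy3, with that of 1 Brpf1-deficient pup, labelled with Cy5, and the labels number the pairs 1 to 3. The labels give 350 ng of total RNA as input to a single round of amplification. Between 59.9% and 61.0% of the 59305 non-control spots were well above background in Cy3, and between 57.9% and 58.2% in Cy5. The median spot signal was 151 to 187.5 in Cy3 over a median background of 42 to 60, and 271 to 307 in Cy5 over a background of 111.5 to 148. After filtering, 32983 of 55681 probes remained, which stood for 23232 genes. With 3 arrays, the number of arrays limits the precision of every value below.

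The targeted gene was examined first. Brpf1 was brighter in the Cy5 channel, which the labels give to the Brpf1-deficient pups, on all 3 arrays, with log2 ratios of Cy5 over Cy3 of 0.63, 0.73 and 0.96. The mean was 0.77 ± 0.17 (SD, n = 3 arrays), a 1.71-fold difference with a limma adjusted p of 0.00446. This direction opposes the authors' deposited table, in which Brpf1 has a log fold change of -0.80, and it goes against the label of the channel. The array carries 1 probe named Brpf1, and whether it lies inside the deleted part of the gene is not known here, so it may check nothing about the genotype. All ratios below are therefore given by channel, as labelled: a positive log2 ratio means brighter in Cy5 (labelled Brpf1-deficient) and a negative ratio brighter in Cy3 (labelled wild type). Every called probe that is also in the authors' deposited table has the opposite sign there, and which genotype each direction belongs to is not settled.

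In total, 3982 of the 23232 genes (17.1%) passed an adjusted p of 0.05 in limma, 1852 of them brighter in Cy5 and 2130 brighter in Cy3. All 3982 had the same sign on all 3 arrays, which passing this test with 3 arrays nearly requires, so it is no separate sign of reproducibility. Most differences were small: 3890 of the called genes (97.7%) differed by under 2-fold, and the median size of a called log2 ratio was 0.38. At least 2-fold, 49 genes were brighter in Cy3 and 43 in Cy5. Of those 49 genes, 21 were not well above background in Cy5 on any array, and of the 43, 19 had very bright probes, with a mean log2 intensity over 16. The log2 ratios of pairs of arrays correlated across genes at Pearson r = 0.566 to 0.703, where genes are not independent replicates. The same dye marked the same genotype on every array, so a dye effect on a gene cannot be separated from genotype. The count was 1858 without array 3. Brighter in Cy5 were 46.5% of the calls after loess, 23.5% with the scanner software's processed signals and 83.4% with median centring.

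The Hox genes, homeobox transcription factors that pattern the trunk and hindbrain along the head-to-tail axis, held the largest differences. The array holds 39 Hox genes, of which 18 passed the filter on dim probes. Of these 18, 15 were brighter in Cy3 and none in Cy5 (16 and 0 adjusted over the list alone). Without the filter, 16 of the 39 were brighter in Cy3 and 1 in Cy5, and 33 had a ratio below 0. Hoxc4 had a log2 ratio of -4.79 ± 0.13 (SD, n = 3 arrays, adjusted p = 1.15e-06), Hoxb13 of -4.27 ± 0.17, Hoxc6 of -3.51 ± 0.11 and Hoxd8 of -3.18 ± 0.07. All 4 were well above background in Cy3 on all 3 arrays and not well above background in Cy5 on any. They were therefore at least 27.3-fold, 18.6-fold, 10.4-fold and 8.29-fold brighter in Cy3. Hoxc9, well above background in Cy5 on 2 arrays, had a log2 ratio of -2.65 ± 0.21. In all, 13 of the 15 called Hox genes were not well above background in Cy5 on any array. The 3 measured genes that did not pass were Hoxd11 (-0.31 ± 0.33), Hoxa9 (-0.06 ± 0.07) and Hoxa4 (-0.03 ± 0.06). The median log2 ratio was -1.30 over the 18 Hox genes that passed the filter (camera adjusted p = 1.11e-17) and -0.22 over all 39 (camera adjusted p = 7.33e-12). The filter keeps a gene that is bright in either channel, so the first median leaves out genes dim in both. With the processed signals the median over the 18 was -2.63, with 14 brighter in Cy3 and none in Cy5. With an estimated correlation the list was not called (adjusted p = 0.673). The list was written down with knowledge that the study reports Hox genes, so its direction is not independent evidence.

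**Figure D1:**
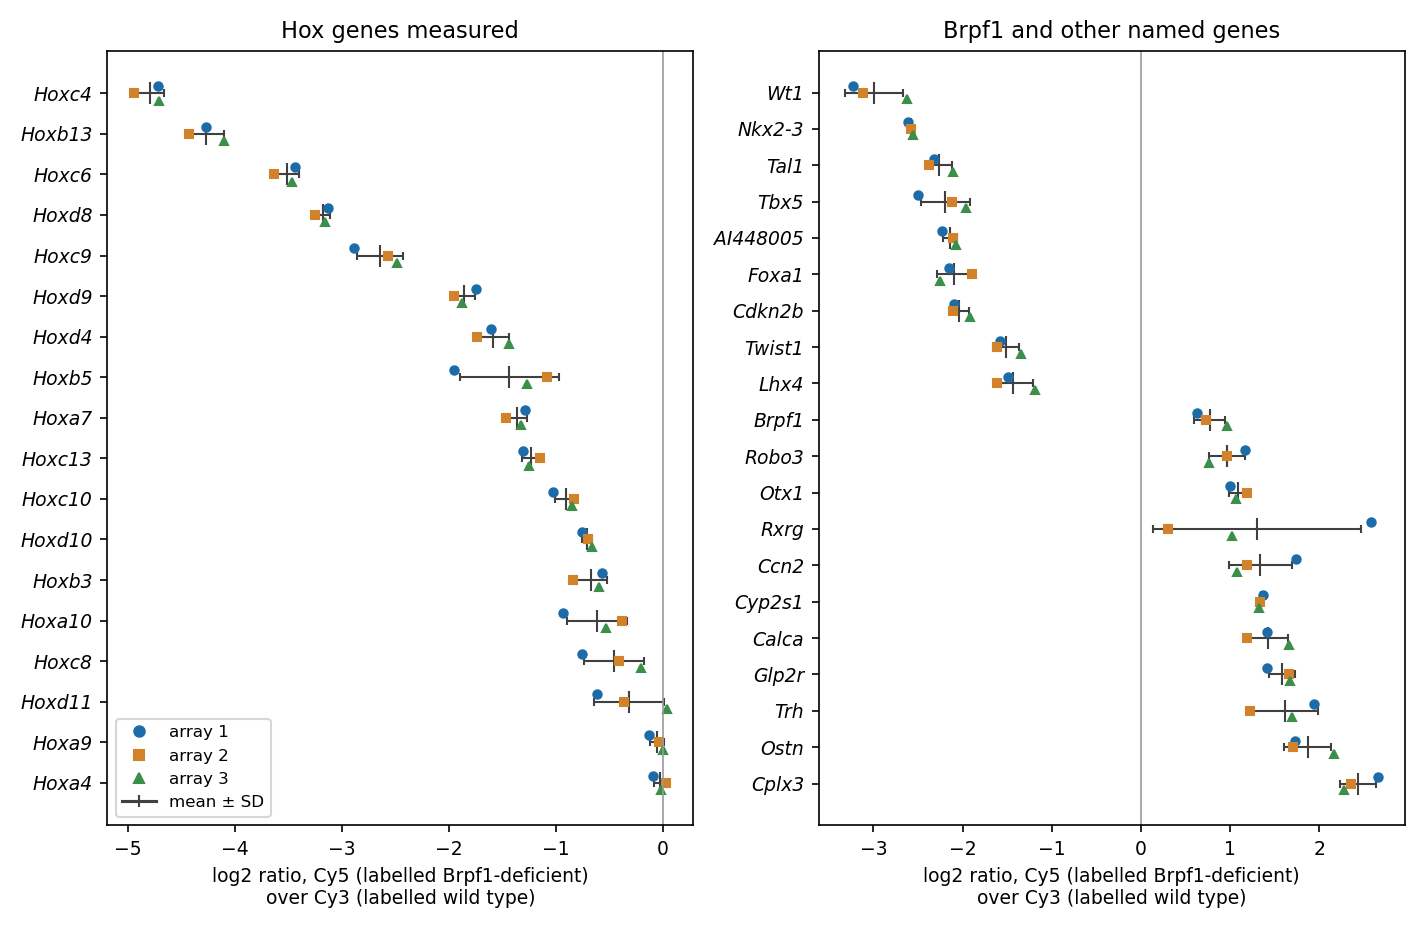
Log2 ratio of Cy5 (labelled Brpf1-deficient) over Cy3 (labelled wild type) on the horizontal axis, for the 18 measured Hox genes (left) and for Brpf1 and other named genes (right, without probes of a mean log2 intensity over 17). Coloured symbols are the 3 arrays, and the vertical tick with its bar is the mean ± SD. Hoxc4 lies near -4.79 and Cplx3 near 2.43, while Hoxa9 and Hoxa4 lie near 0.

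The 12 largest differences towards Cy3 also held 5 genes that are neither Hox genes nor recalled from the study. Wt1, a zinc-finger transcription factor of kidney and gonad development, had a log2 ratio of -2.99 ± 0.32 (SD, n = 3 arrays). It was well above background in Cy5 on only 1 array. The homeobox gene Nkx2-3 had -2.58 ± 0.03, and Tal1, a transcription factor of blood cell formation, -2.27 ± 0.15. Cdkn2b, an inhibitor of cell cycle progression, had -2.04 ± 0.11, and the expressed sequence AI448005 had -2.14 ± 0.08. The adjusted p of these 5 genes lay between 6.56e-06 and 5.25e-05. AI448005 was not well above background in Cy5 on any array and was at least 4.40-fold brighter in Cy3.

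A further 6 genes were named in advance because they are recalled from the study's publication, so they are not independent evidence. Tbx5, a regulator of heart and forelimb development, had a log2 ratio of -2.19 ± 0.28 (SD, n = 3 arrays). Foxa1, a forkhead factor of endoderm and the ventral midbrain, had -2.10 ± 0.19, Twist1, a factor of mesoderm, -1.51 ± 0.15, and the LIM homeobox gene Lhx4 -1.43 ± 0.22. Tbx5 was at least 4.57-fold and Foxa1 at least 3.61-fold brighter in Cy3, as neither was well above background in Cy5. In contrast, Otx1, a homeobox gene of the developing cortex, was brighter in Cy5 at 1.09 ± 0.10, and so was Robo3, a receptor in the midline crossing of axons, at 0.96 ± 0.20. Otx1 was well above background in Cy3 on 2 arrays. The adjusted p of the 6 genes was between 6.69e-05 and 0.00219. As a list they leaned to Cy3 (camera adjusted p = 0.0492), and adjusted over the list alone all 6 passed. The lean was not called with an estimated correlation (adjusted p = 0.673), nor under 6 other settings (adjusted p = 0.0524 to 0.274, the highest with the processed signals).

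Regulators of other body regions did not move as a group. Of 25 measured patterning factors that lie outside the Hox clusters and mark tissues other than cortex, 4 were brighter in Cy3, none in Cy5 and 21 did not pass (4 and 0 adjusted over the list alone). Among the 4 were En2, a midbrain and hindbrain factor (-0.97 ± 0.14, SD, n = 3 arrays), Tbx3 (-0.64 ± 0.23) and Tbx4 (-0.30 ± 0.14). En2 was not well above background in Cy5 on any array and was at least 1.90-fold brighter in Cy3. The list's median was 0.02, its mean -0.08, and camera gave an adjusted p of 0.698.

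Brighter in Cy5, the largest ratio was that of Cplx3, a complexin of presynaptic terminals and a marker of subplate neurons, at 2.43 ± 0.20 (SD, n = 3 arrays, adjusted p = 3.91e-05). Genes for secreted peptides and their receptors followed: Ostn, encoding osteocrin, at 1.87 ± 0.26, Trh, encoding thyrotropin-releasing hormone, at 1.62 ± 0.37, the gut hormone receptor Glp2r at 1.58 ± 0.15, and Calca, encoding calcitonin and a related neuropeptide, at 1.42 ± 0.23. Glp2r was well above background in Cy3 on only 1 array and Ostn on 2, so their ratios rest in part on dim Cy3 signal. The cytochrome gene Cyp2s1 had 1.34 ± 0.02, and Ccn2, a secreted matrix protein also used as a subplate marker, 1.33 ± 0.35. Rxrg, a retinoid receptor of the striatum, had 1.30 ± 1.16 with array values of 2.58, 0.30 and 1.02. Its adjusted p was 0.0495, and 0.0538 without array 1. The 12 largest also held Calm2, encoding calmodulin (1.31 ± 0.17), the actin gene Actb (1.35 ± 0.06) and Ppia, encoding cyclophilin (1.35 ± 0.19). These 3 probes had mean log2 intensities between 17.29 and 17.48, where most probes leaned to Cy5.

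Among progenitor genes, those of intermediate progenitors, the dividing cells that give rise to cortical neurons, leaned to Cy5. Of 11 measured, 3 were brighter in Cy5 and none in Cy3 (4 and 0 adjusted over the list alone): Sstr2 at 0.61 ± 0.07 (SD, n = 3 arrays), Gadd45g at 0.43 ± 0.11 and Mfap4 at 0.37 ± 0.13. The list's median was 0.24 (camera adjusted p = 0.00130). That call was lost with an estimated correlation (adjusted p = 0.673), under which 0 of the 32 lists were called. It was kept under 15 other camera settings, but fry did not call the list (adjusted p = 0.0958). Of 17 radial glia and neural stem cell genes, 4 were brighter in Cy5 and 2 in Cy3 (5 and 4 adjusted over the list alone, camera adjusted p = 0.638). They included the cortical selector genes Lhx2 at 0.44 ± 0.10 and Emx2 at 0.35 ± 0.14, and Notch1 at -0.86 ± 0.47 (second probe -0.25). Fabp7 had 0.31 ± 0.10, but -0.12 with the processed signals. Of 31 cell cycle genes, 5 were brighter in Cy5 and none in Cy3, also when adjusted over the list alone (camera adjusted p = 0.0833). Ccne1 had 0.33 ± 0.11, with a second probe at 0.01, Mcm5 0.29 ± 0.08, Ccnd2 0.31 ± 0.11 and Ccnd1 0.33 ± 0.14.

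Inhibitors of the cell cycle and targets of p53 went both ways: 3 of 17 were brighter in Cy3 and 1 in Cy5, also when adjusted over the list alone (camera adjusted p = 0.348). The neighbouring inhibitor genes Cdkn2b and Cdkn2a stood apart, at -2.04 ± 0.11 and -1.91 ± 0.16 (SD, n = 3 arrays), and a second probe of each was brighter in Cy3 as well (-1.45 and -0.92). The reported Cdkn2a probe was well above background in Cy5 on only 1 array. Trp53inp1 had -0.35 ± 0.06, with a second probe at 0.05, and Sesn2 0.27 ± 0.11. Of 13 genes for partners of BRPF1 and related acetyltransferases, 1 passed, also when adjusted over the list alone (camera adjusted p = 0.698). It was Jade1, at -0.39 ± 0.08, whose second probe had 0.05.

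Markers of cortical neurons leaned to Cy5 with members in both directions. Of 15 upper-layer genes, 6 were brighter in Cy5 and 3 in Cy3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0492). The nuclear receptor gene Rorb had 1.04 ± 0.05 (SD, n = 3 arrays), Lmo4 0.76 ± 0.12 and Pou3f2 0.37 ± 0.04, while the axon guidance receptor Epha3 had -0.85 ± 0.39. With an estimated correlation the upper-layer call was lost (adjusted p = 0.727). Of 18 deep-layer and subplate genes, 7 were brighter in Cy5 and 3 in Cy3 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0492). Beside Cplx3 at 2.43 ± 0.20 and Ccn2 at 1.33 ± 0.35, they included Etv1 at 0.48 ± 0.13 (second probe 0.01) and Syt6 at 0.86 ± 0.46. This call too was lost with an estimated correlation (adjusted p = 0.673), while fry called the deep-layer and subplate list (adjusted p = 0.012). The upper-layer call was also lost under 7 other settings (adjusted p = 0.0526 to 0.168) and the deep-layer call under 3 (adjusted p = 0.0524 to 0.0769).

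Interneuron genes went both ways, with 6 of 18 brighter in Cy3 and 3 in Cy5 (7 and 3 adjusted over the list alone, camera adjusted p = 0.195). The neuropeptide gene Npy had 0.83 ± 0.24 (SD, n = 3 arrays), while Dlx1 had -0.56 ± 0.14, Maf -0.57 ± 0.19 (second probe -0.21) and Erbb4 -0.45 ± 0.12 (second probe -0.12). Of 34 axon guidance and callosal genes, 8 were brighter in Cy3 and 5 in Cy5 (14 and 7 adjusted over the list alone, camera adjusted p = 0.311). Among them were Sema3c at -0.75 ± 0.24, Epha5 at -0.48 ± 0.07 (other probes -0.66 and -0.04), Robo1 at -0.39 ± 0.11 and Efna3 at 0.45 ± 0.17. The beta protocadherins, cell surface proteins from a gene cluster, leaned to Cy3: 4 of 21 were brighter there and none in Cy5 (6 and 0 adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.00130), and Pcdhb17 had -0.50 ± 0.18 and Pcdhb16 -0.45 ± 0.15. The call was lost with an estimated correlation (adjusted p = 0.727). It was kept under 15 other camera settings, but fry did not call the list (adjusted p = 0.139). Of 23 synapse genes, 2 were brighter in Cy5 and 3 in Cy3, also when adjusted over the list alone (camera adjusted p = 0.811). Gria2 had -0.69 ± 0.20, Gria1 -0.34 ± 0.07, Snap25 -0.44 ± 0.24 and Nrgn 0.58 ± 0.15.

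Genes of neighbouring brain regions were examined next. Of 11 genes of the striatum, which lies beneath the dorsal cortex, 7 were brighter in Cy5 and none in Cy3 (9 and 0 adjusted over the list alone, camera adjusted p = 4.75e-05). Penk had 1.08 ± 0.56 (SD, n = 3 arrays), Ebf1 0.60 ± 0.24, Adora2a 0.71 ± 0.41 and Tac1 0.83 ± 0.54. The array values of Penk were 1.55, 0.46 and 1.22. Members moved together from array to array, with an estimated correlation between genes of 0.963, and the call was lost when it was used (adjusted p = 0.727). It was kept under 15 other camera settings, but fry did not call the striatum list (adjusted p = 0.245). Of 11 thalamus genes, 3 were brighter in Cy3 and 1 in Cy5, also when adjusted over the list alone (camera adjusted p = 0.705): Slc17a6 at -0.83 ± 0.12, Ntng1 at -0.51 ± 0.07, Calb2 at -0.48 ± 0.29 and Prkcd at 0.53 ± 0.08. Of 12 hippocampal genes, 1 passed, also when adjusted over the list alone (camera adjusted p = 0.348), C1ql2 at 0.44 ± 0.16. Of 12 choroid plexus genes, 1 passed, also when adjusted over the list alone, Prlr at -0.57 ± 0.38 (-0.999, -0.433 and -0.272 on the 3 arrays), with a second probe at -0.03. For this list the median (-0.0033) and the direction of camera (Cy5, adjusted p = 0.761) differed in sign.

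Of 14 microglia genes, 3 were brighter in Cy5 and none in Cy3, also when adjusted over the list alone (camera adjusted p = 0.0492): the complement genes C1qb at 0.36 ± 0.22 (SD, n = 3 arrays) and C1qa at 0.32 ± 0.19, and Cd68 at 0.33 ± 0.21. The microglia call was lost with an estimated correlation (adjusted p = 0.757) and without array 1 or array 3 (adjusted p = 0.0680 and 0.217). Of 8 erythroid genes, 2 were brighter in Cy5 (4 adjusted over the list alone, camera adjusted p = 0.0118), the globin genes Hba-a1 at 1.10 ± 0.55 and Hba-a2 at 1.10 ± 0.53. The values of Hba-a1 were 0.88, 0.71 and 1.73 on the 3 arrays, and the list's call was lost with an estimated correlation (adjusted p = 0.727) and without bright probes (adjusted p = 0.281). Of 12 astrocyte genes, Slc1a3 (-0.38 ± 0.05) and Gfap (-0.32 ± 0.05, other probes -0.22 and 0.07) were brighter in Cy3 and Apoe (0.35 ± 0.19) in Cy5 (4 and 1 adjusted over the list alone, camera adjusted p = 0.311). After the median of each intensity bin was set to 0, 2 astrocyte genes were brighter in Cy3 and 0 in Cy5, so the Apoe call was lost. Of 8 Cajal-Retzius cell genes, Cacna2d2 (0.40 ± 0.21, second probe 0.18) and Reln (0.34 ± 0.22) were brighter in Cy5 and Nhlh2 (-0.47 ± 0.24) in Cy3, also when adjusted over the list alone (camera adjusted p = 0.705). Cldn5 (0.30 ± 0.14) passed among 12 endothelial and mural cell genes, where none passed when adjusted over the list alone (camera adjusted p = 0.109). None of 13 oligodendrocyte lineage genes and none of 12 genes of meninges and fibroblasts passed in limma, also when adjusted over the list alone (camera adjusted p = 0.102 and 0.126). At an unadjusted p under 0.05, 3 of the 13 and 3 of the 12 passed.

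**Figure D2:**
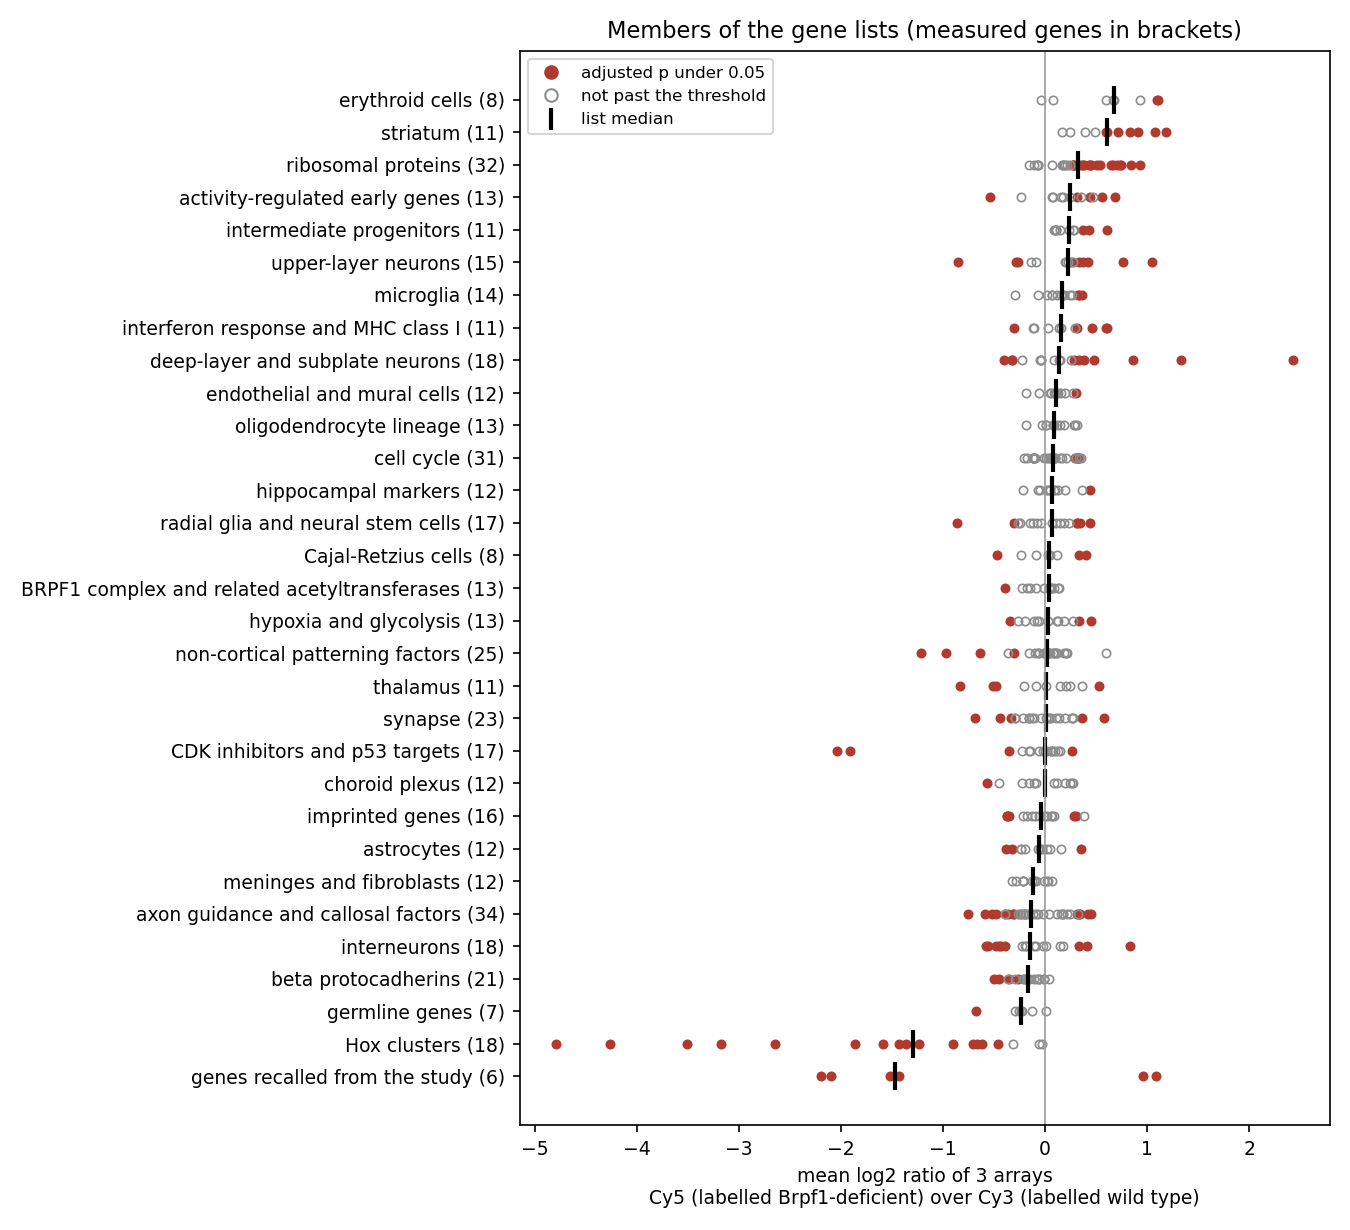
Mean log2 ratio of Cy5 over Cy3 (horizontal axis) of each measured member of 31 gene lists (vertical axis, ordered by median, measured members in brackets). Filled points passed an adjusted p of 0.05, open points did not, and the black tick is the list's median. The Hox clusters and the genes recalled from the study lie lowest, with medians of -1.30 and -1.47, and the erythroid genes highest, at 0.67.

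Of 13 activity-regulated early genes, 4 were brighter in Cy5 and 1 in Cy3 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0281). Egr2 had 0.69 ± 0.17 (SD, n = 3 arrays), Ier2 0.56 ± 0.10, Junb 0.31 ± 0.16 and Fosl2 -0.54 ± 0.09 (second probe -0.16). The call was lost with an estimated correlation (adjusted p = 0.727) and without array 1 or array 3 (adjusted p = 0.0680 and 0.0503), and also with median centring (adjusted p = 0.168). Among 11 interferon response and MHC class I genes, 4 were brighter in Cy5 and 1 in Cy3 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0683), led by H2-K1 at 0.61 ± 0.07 and H2-D1 at 0.59 ± 0.11. Of 16 imprinted genes, 3 were brighter in Cy3 and 2 in Cy5 (3 and 3 adjusted over the list alone, camera adjusted p = 0.665). They were led by Plagl1 at -0.37 ± 0.07 (other probes -0.39, 0.09 and 0.15) and Impact at -0.37 ± 0.08, and Nnat at -0.35 ± 0.03 changed sign under median centring (0.06). Of 13 hypoxia and glycolysis genes, Ndrg1 (-0.34 ± 0.10) was brighter in Cy3 and Car9 (0.45 ± 0.23) and Ldha (0.33 ± 0.05) in Cy5 (2 in each direction adjusted over the list alone, camera adjusted p = 0.724). Ldha had -0.02 with the processed signals. Of 7 germline genes, Tdrd1 was brighter in Cy3 at -0.67 ± 0.40 (3 adjusted over the list alone, camera adjusted p = 0.0492). This call was lost with an estimated correlation (adjusted p = 0.673) and under 7 other settings (adjusted p = 0.0505 to 0.149).

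Ribosomal protein genes leaned to Cy5, with 20 of 32 brighter there and none in Cy3 (24 and 0 adjusted over the list alone) and a median of 0.32 (camera adjusted p = 1.23e-09). Rpl10 had 0.94 ± 0.10 (SD, n = 3 arrays) and Rps14 0.75 ± 0.19. The call was lost with an estimated correlation (adjusted p = 0.673). It was also lost when the median log ratio of each intensity bin was set to 0, where 3 members were brighter in Cy5, 1 in Cy3 and the camera adjusted p was 0.30. With the processed signals the list's median was -0.08 (camera adjusted p = 0.320). These genes have very bright probes, and probes of that brightness leaned to Cy5 as a whole. The 614 genes with a mean log2 intensity of 16 to 17 had a median log2 ratio of 0.19, and the 87 genes above 17 a median of 0.80.

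**Figure D3:**
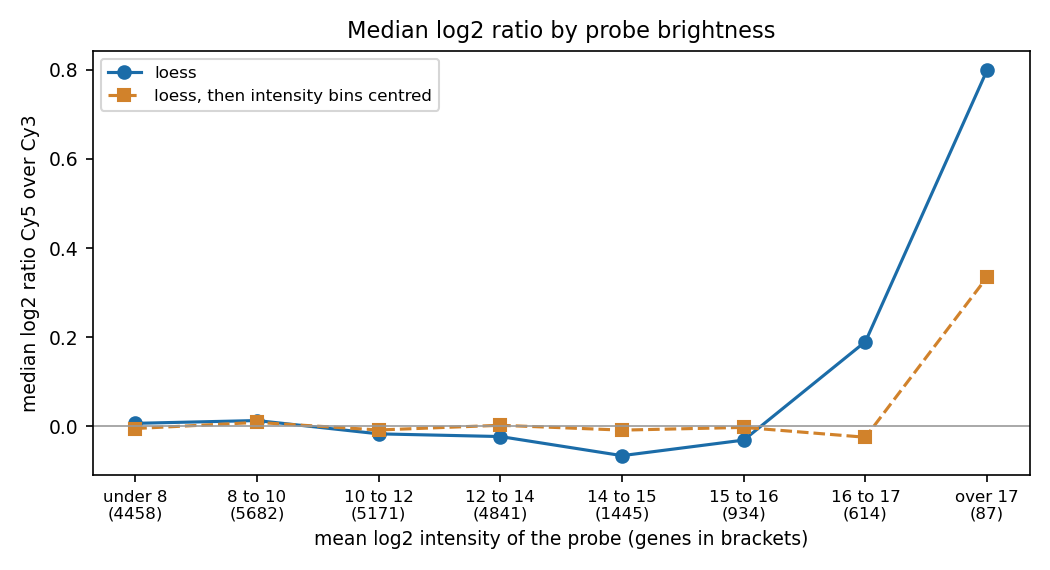
Median log2 ratio of Cy5 over Cy3 (vertical axis) of genes grouped by the mean log2 intensity of their probe (horizontal axis, number of genes in brackets). The solid line shows values after loess and the dashed line values after the median of each intensity bin was also set to 0. Genes above 17 had a median of 0.80 after loess and 0.33 after the second step.

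The authors' deposited table was set beside these values. It lists 40000 rows, with p up to 0.458, so it holds only part of the array. Its log fold changes and the log2 ratios of Cy5 over Cy3 correlated at Pearson r = -0.938 across the 23924 probes found in both. All 5557 of these probes that passed an adjusted p of 0.05 in limma had the opposite sign in the authors' deposited table. In that table Hoxc4 has a log fold change of 7.17, Foxa1 of 5.53, Tbx5 of 4.48, Otx1 of -1.87 and Robo3 of -1.67. The smallest adjusted p in the authors' deposited table is 0.159, so 0 rows lie under 0.05, while 9796 rows have an unadjusted p under 0.05.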

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

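The intensity-bin setting and the one without bright probes were chosen after the data had been seen. The 3982 calls (1852 brighter in Cy5, 2130 in Cy3) became 1849 (435 and 1414) with the scanner software's processed signals, which moved the median log2 ratio of all genes to -0.11. Median centring in place of loess gave 4466 brighter in Cy5 and 891 in Cy3. Fitting the 6 channels separately, without the pairing by array as a block, gave 172 (109 and 63). The pairing is that of the array itself. Leaving out each array gave 1858 to 3799 calls, 761 to 1619 brighter in Cy5 and 1097 to 2180 in Cy3, with fewer arrays tested. Stricter or looser thresholds gave 611 calls (293 and 318) at 1.5-fold or more, 6954 (3278 and 3676) at an adjusted p under 0.10 and 8547 (4030 and 4517) at an unadjusted p under 0.05. The authors' deposited table has 0 rows under an adjusted p of 0.05. All other alternatives stayed within 1.5 times the count. The cause of these shifts was not tested beyond the change of setting. Brpf1 kept its direction and its call under every alternative run, at log2 ratios from 0.68 to 0.85 and adjusted p up to 0.0438.

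Of 32 lists, 12 were called by camera with the preset correlation, 0 with an estimated correlation, 3 by fry and 7 without bright probes. Leaving out each array gave 9 to 15. With an estimated correlation even the Hox clusters were not called, so a call lost there does not decide whether a list shifted. A call at the preset correlation does not decide it either where list members vary together, because the simulation held no such lists. The 3 lists called by fry were the Hox clusters, the genes recalled from the study, and the deep-layer and subplate neurons. Of 111 other named genes, 57 kept their direction and call under all 5 other scalings and 79 without each array in turn. Reversed were Fabp7 (-0.12), Ldha (-0.0181) and Snrpn (-0.0641) with the processed signals, Nnat (0.0614) with median centring and Fabp7 (-0.15) with intensity bins, and the cause was not tested. Of 37 named genes with further probes, 7 had a probe of the opposite sign and 18 another called probe of the same sign. The slide could not be fitted as a block, because all arrays lie on 1 slide, and the correction for probe base composition was not run, because the files used here hold no probe sequences. Signal over background limits the ratios of the 21 genes at least 2-fold brighter in Cy3 that were not well above background in Cy5.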

Other observations

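The genes in this paragraph lie outside the naming rule, were chosen after their values were seen and stand for no group. Brighter in Cy3 (labelled wild type), the neuronal and hepatic transcription factors Onecut1 and Onecut2 had log2 ratios of Cy5 over Cy3 of -2.02 and -1.90, Pax1, a factor of the vertebral column, -1.70, Hmx1 -1.56, Barx1 -1.31 and the sensory neuron factor Pou4f1 -1.26. Onecut1, Pax1, Hmx1 and Barx1 were not well above background in Cy5 on any array, and were at least 4.07-fold, 3.19-fold, 2.95-fold and 1.91-fold brighter in Cy3. Pou4f1 was well above background in Cy5 on only 1 array. The retinoic acid synthesis gene Aldh1a3 had -1.91. Adjusted p in limma lay between 7.67e-05 and 0.00164. Brighter in Cy5 were the neuropeptide genes Pdyn at 1.14 and Nts at 1.13, and Lefty2 at 1.23, with adjusted p of 0.0135, 0.00167 and 0.000253.

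The pups on each array differed in the expression of sex-linked genes, and by these values each array paired a female with a male pup. The Cy5 pup was the female on arrays 1 and 3 and the male on array 2. The fit held no term for sex, so sex differed within every pair behind the calls above. Ddx3y and Eif2s3y, both on the Y chromosome, had log2 ratios of -5.33 and -6.57 on array 1, 5.44 and 5.88 on array 2, and -5.56 and -6.30 on array 3. Xist, expressed from the inactive X chromosome, had 4.24, -4.83 and 5.18. None of the 5 listed sex-linked genes passed over the 3 arrays in limma, also when adjusted over the list alone (camera adjusted p = 0.601), and 0 passed at an unadjusted p under 0.05. Because their signs turned on array 2, this outcome says nothing about whether sex affected other genes. An effect of sex alone would likewise turn on array 2, while all 3982 called genes had the same sign on all 3 arrays. That argues against sex alone as the source of these calls. A contribution of sex to the size of their ratios is not excluded.

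The tests below were chosen after the results they concern were seen. The predictions for intensity bins and for neighbouring genes were written before those tests were run, the former after the lean of bright probes had been seen. Brpf1 was brighter in the channel labelled Brpf1-deficient on all 3 arrays, while Hox genes were detected mainly in the channel labelled wild type. An exchange of dyes on a single array would turn the Hox genes there, as it would the sex-linked genes, which did turn on array 2. It is argued against by the median log2 ratio of the 18 Hox genes, which was -1.30, -1.11 and -1.26 on the 3 arrays, unless dye bias reaches that size. The correlation between arrays (lowest r = 0.566 across genes) does not decide this, because a dye bias shared by the arrays also gives a positive r. An exchange of the genotype labels for all 3 arrays may account for the pattern: the authors' log fold changes run opposite to Cy5 over Cy3 (r = -0.938 across probes), and their Brpf1 value is negative. The authors could also have turned the ratio, which the correlation alone does not exclude. Whether the Brpf1 probe lies outside the deleted part, with more transcript from the changed allele, cannot be told apart from this, because 0 other Brpf1 probes were measured.

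Most calls were under 2-fold, with dye and genotype confounded. Dye bias specific to each probe gives a shared direction in about 50% of genes if the 2 probes of a gene have independent bias. There were 626 such called genes with a second RefSeq-named probe and neither probe over a log2 intensity of 15. Their second probe shared the direction in 80.0% (exact 95% interval 76.7 to 83.1%). That argues against such bias as the whole cause only where the 2 probes do not overlap, which could not be checked without probe sequences. The share of second probes with the same direction was 61.5% among genes not called. At least 2-fold, it was 8 of 8. Dye bias of whole transcripts, which 2 probes of a gene could share, cannot be told apart from genotype, because 0 arrays had swapped dyes. Biological differences between pups of the 2 genotypes stay open as well.

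The lean of ribosomal protein genes to Cy5 may reflect an intensity trend left by loess at the bright end. For other very bright probes such a trend may account for part of the lean. After centring on intensity bins, 3 of the 20 called ribosomal protein genes were still called as brighter in Cy5. Above a log2 intensity of 17 the median log2 ratio was 0.80 before and 0.33 after that step. Of the 87 genes there, 83 were called as brighter in Cy5 before it and 48 after it, so the lean was reduced and not removed. A difference in ribosomal protein transcripts between the genotypes was not tested apart from this trend. Centring the bright bins would also remove a difference that these bright probes share.

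A hypothesis was tested that genes at least 2-fold brighter in Cy3 lie beside each other outside the Hox clusters. With Hox genes, 39 such named genes formed 5 adjacent pairs, against a mean of 0.0907 in 10000 random draws (permutation p = 1e-04, the smallest the draws can give). Hox genes lie in clusters and were already known to be called, so this p-value does not bear on the hypothesis. Without Hox genes, 29 formed 1 adjacent pair, Cdkn2a and Cdkn2b (permutation p = 0.05), which is too few to decide whether neighbouring genes changed together there.

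Of the 4 ways to turn the signs of the 3 arrays that differ in more than direction, the real one gave 3982 genes and the highest of the others 6. With 4 ways, 1 of which is the real one, no share under 0.05 can be reached.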
